A study of Danio rerio with 24 samples.

How the data were processed

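The deposited files held raw counts per gene, made by the authors with featureCounts 1.4.6-p4 from STAR 2.4.1d alignments to GRCz10 after base calling with CASAVA 1.8.2, according to the submitters' processing notes. They also held values the authors named RPKM. Libraries were made from total liver RNA with the TruSeq RNA v2 kit, and the strand setting of the counting is not stated. The fits used the counts. The counts came in 2 tables, with the 3.75 nM fish in one and all fish at 37.5 nM in the other, and were joined on gene identifier into 32105 gene rows, 26269 of them with a symbol in the reference table. No row named anything but a gene, and every deposited sample column was used.

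The deposited RPKM-named values were not RPKM as named, and were used only as an alternative unit. For 3244 genes with counts of at least 300, the divisor from count to deposited value repeated every 44 rows (SD of the log ratio 3.55e-05, against 0.174 or more at any other period). The divisors matched library totals (SD 8.88e-06), 24 of them totals of the libraries used here, with 20 others. The division had therefore been recycled down the rows instead of along the columns, which adds an error with an SD of 0.316 log2 per value. The same 44 divisors ran through the values of both tables, so the RPKM-named values of all libraries had been calculated as 1 set. That does not show whether the libraries were prepared or sequenced together.

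Counts were scaled with TMM factors, filtered with filterByExpr and tested with the two-sided quasi-likelihood F test of edgeR 4.0.16, separately for each comparison, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the absolute log2 change divided by the square root of F. The biological coefficient of variation was 0.510 in the age comparison and 0.535 in the dose comparison. Between replicates, the lowest chi-square per gene of any pair was 89.3, so no pair repeated another within counting noise. CPM values are means with SD over fish.

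Before the data were seen, 50 gene lists were written, 32 of pathways and 18 of cell types, and 1597 of their 1728 entries matched a gene row (1317 by symbol, 125 by synonym and 155 by symbol stem). Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, then with an estimated correlation, and with fry. An exact two-sided permutation of each list's mean log2 CPM over all fish (48620 splits for dose, 5005 for age) and within number series (17640 and 1890) was added after the data were seen. In the list of mitochondrial stress, 11 gene rows carried the symbol HTRA2, but most of them were not tested. Without them the tested genes went from 30 to 29. The camera adjusted p of the list at the preset correlation was then 0.00206 in the age comparison and 0.0786 in the dose comparison. With an estimated correlation the full list had an adjusted p of 0.886 and 0.857.

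Genes were named by a rule set beforehand: the 10 highest and 10 lowest log2 changes past the threshold with a mean of at least 4 CPM, up to 4 genes per list, and 8 genes named in advance. Only 2 per list were taken, a choice made after the data were seen, and a few genes that the rule picked are not described here. Alternatives used RLE, upper-quartile and library-size scaling, other filters, 1 library left out at a time, number series as a covariate or alone, DESeq2 1.42.0, limma voom with quality weights and limma-trend on the deposited RPKM-named values. Alternatives added after the data were seen left out libraries with an intestine score above 2, added marker scores as covariates, left out fish 189, or ran DESeq2 and voom per number series.

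In simulated data with the same libraries, edgeR recovered 34% of 100 genes changed by 1 log2 and 75% of 100 changed by 2 log2 in the age design, with 3 false calls among 115. In the dose design it recovered 40% and 72%, with 3 false calls among 119. DESeq2 recovered 49% and 85% with 43 false calls among 187 in the age design. All list tests recovered a simulated list of 40 genes lowered by 0.7 log2. In the dose design both permutation tests also called 1 other list. Genes were drawn independently of each other and without number series. The recovery therefore cannot show how the list tests handle correlated genes. Work was done in R 4.3.3 and Python 3.11.15.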

Results

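RNA was sequenced from the livers of 24 male zebrafish, with 1 library per fish. The labels give every fish a rotenone concentration. Rotenone is an inhibitor of mitochondrial complex I. The fish formed 3 groups: 9 fish aged 1 year at 3.75 nM, 9 fish aged 1 year at 37.5 nM and 6 fish aged 3 years at 37.5 nM. No label names an untreated fish, so no value below has an untreated background beside it, and the length of exposure is not stated. The 3-year fish carried a transgene, Tg(flk:mCherry), on the same AB JxTu background as the 1-year fish, so age and the transgenic line could not be told apart. Fish numbers in the titles ran from 163 to 181 and from 189 to 202, called the lower and upper number series here, and the labels do not say what separated them. If fish of one series had a treatment that the labels leave out, such as vehicle alone, the groups here pool both. The lower series held 4 fish at 3.75 nM, 4 one-year fish at 37.5 nM and 2 three-year fish, and the upper series held 5, 5 and 4. Total counts per library ranged from 24644663 to 45297644, with medians of 30947554 for 1-year fish at 3.75 nM, 34871346 for 1-year fish at 37.5 nM and 37919986 for 3-year fish. Each library came from its own fish, so the p-values set differences against the spread between fish. All fish at 3.75 nM were deposited in 1 count table and all fish at 37.5 nM in another. Dose and any difference between those 2 sets could therefore not be told apart, and no p-value here covers it.

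The first comparison set 1-year fish at 37.5 nM against 1-year fish at 3.75 nM (n = 9 each), and the sign of every change in it is 37.5 nM minus 3.75 nM. Genes that build ribosomes, fold proteins and make cholesterol were lower at 37.5 nM. HSPA5 (ENSDARG00000103846), the main chaperone of the endoplasmic reticulum (ER), fell by 3.10 ± 0.56 on the log2 scale (estimate ± SE), from 744 ± 596 to 86.8 ± 36.4 CPM (counts scaled to a common library total, mean ± SD). GNL3 (ENSDARG00000006219), a nucleolar protein of ribosome production, fell by 1.49 ± 0.24, from 37.5 ± 17.1 to 13.3 ± 2.27 CPM. MVK (ENSDARG00000004130), mevalonate kinase of the cholesterol pathway, fell by 2.54 ± 0.54, from 15.3 ± 9.56 to 2.62 ± 2.68 CPM. The edgeR adjusted p-values of HSPA5, GNL3 and MVK were 0.00663, 0.00602 and 0.00913, and 5, 8 and 8 of the 9 fish at 37.5 nM lay below every fish at 3.75 nM.

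In the ribosome biogenesis list, 28 of 44 tested genes fell, 0 rose and 16 did not pass the test, with a median log2 change of −0.73 (32 fell adjusted over the list alone). NOC3L (ENSDARG00000002487), a factor that matures the large ribosomal subunit, fell by 0.80 ± 0.12 (adjusted p = 0.00602), and all 9 fish at 37.5 nM lay below all 9 at 3.75 nM. In the ER unfolded protein response list, 19 of 34 genes fell and 15 did not pass, with a median of −0.99 (28 fell adjusted over the list alone). DNAJB9 (ENSDARG00000016886, a symbol shared by 2 genes), an ER co-chaperone, fell by 3.36 ± 0.54 (adjusted p = 0.00602), in 8 of 9 fish beyond the other group. In the list of heat shock proteins and chaperones, 15 of 27 genes fell and 12 did not pass, with a median of −0.75 (17 fell adjusted over the list alone). HSPA4 (ENSDARG00000004754, also a shared symbol), a cytosolic chaperone that exchanges nucleotide on Hsp70 proteins, fell by 3.24 ± 0.53 from 206 ± 187 to 21.7 ± 7.13 CPM. HSP90AA1 (ENSDARG00000024746), the stress-inducible form of Hsp90, fell by 4.88 ± 0.93 from 94.4 ± 119 to 3.20 ± 0.678 CPM. In the list of cholesterol synthesis and uptake, 10 of 25 genes fell and 15 did not pass, with a median of −1.32 (17 fell adjusted over the list alone). EBP (ENSDARG00000046098), a sterol isomerase, fell by 2.06 ± 0.47, from 104 ± 73.6 to 24.9 ± 21.4 CPM, and the adjusted p-values of HSPA4, HSP90AA1 and EBP were 0.00602, 0.00697 and 0.0122.

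These 4 lists (ribosome biogenesis, ER unfolded protein response, heat shock and cholesterol synthesis, in that order) passed camera with its preset correlation at adjusted p = 8.1e-17, 2.2e-12, 1.9e-06 and 7.2e-09. None passed with an estimated correlation (adjusted p = 0.857 with an estimated correlation for each of the 4). They passed limma's fry at adjusted p = 0.0024, 0.0404, 0.0487 and 0.0404. They also passed an exact two-sided permutation of fish over each list's mean log2 CPM, a test chosen after the data were seen, at adjusted p = 0.0226, 0.0386, 0.0298 and 0.037, and the same permutation within number series at 0.00567, 0.00567, 0.00567 and 0.0193. Leaving out 1 library at a time, the permutation call of ribosome biogenesis was kept in 18 of 18 fits. The calls of heat shock, cholesterol and ER response genes were kept in 11, 8 and 5 of 18, and without y1_high replicate 9 the adjusted p of each was 0.0787. The list medians were −0.72, −1.05, −1.32 and −1.18 in the lower number series and −0.66, −0.72, −0.42 and −1.23 in the upper.

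**Figure D1:**
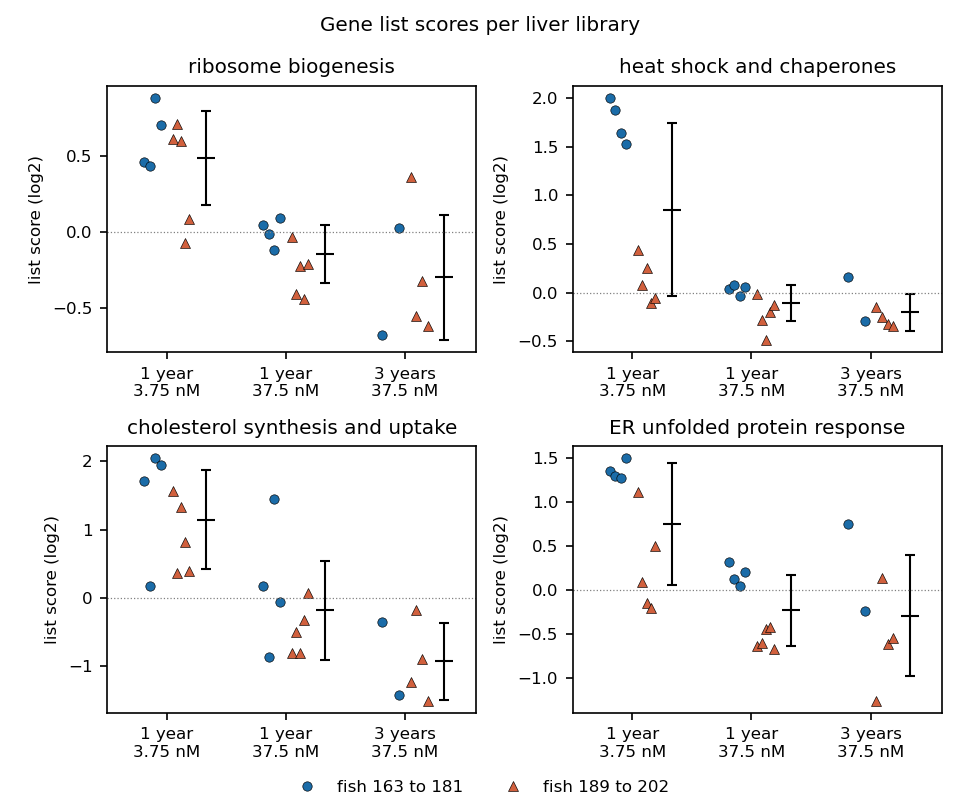
Score of 4 gene lists in each library (mean over the list of each gene's log2 CPM after centring, vertical axis in log2 units) for 1-year fish at 3.75 nM, 1-year fish at 37.5 nM and 3-year fish at 37.5 nM, with circles for fish 163 to 181, triangles for fish 189 to 202, and a bar with whiskers for the mean ± SD. Ribosome biogenesis was lower at 37.5 nM in both number series (median log2 change −0.72 and −0.66), while the heat shock list differed more in the lower series (−1.32) than in the upper (−0.42).

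Other lists passed camera with the preset correlation but not with an estimated one, where the adjusted p was 0.857 except as stated. In the proteasome list, 11 of 41 genes fell and 30 did not pass (25 fell adjusted over the list alone), with a median of −0.35 (camera adjusted p = 4.4e-10). PSMC3 (ENSDARG00000007141), an ATPase of the regulatory particle, fell by 0.84 ± 0.21. Among nuclear genes of the respiratory chain, 2 of 38 complex I subunits fell and 36 did not pass (0 adjusted over the list alone). In complexes II to V, 4 of 46 subunits fell and 42 did not pass (4 adjusted over the list alone). The medians were −0.12 and −0.13. Their camera adjusted p-values were 0.00164 and 0.000606 (adjusted p = 0.905 with an estimated correlation for complex I). Neither list passed the exact permutation (adjusted p = 0.263 and 0.173). Cytochrome c, cycsb (ENSDARG00000044562), fell by 1.59 ± 0.38 (adjusted p = 0.0147), while the complex I core subunit NDUFS1 (ENSDARG00000028546) had a log2 change of −0.10 ± 0.11 (adjusted p = 0.555). Of 23 genes of the TCA cycle, 2 fell, 21 did not pass and 5 fell adjusted over the list alone (median −0.20, camera adjusted p = 0.00774). IDH3A (ENSDARG00000030278), a subunit of isocitrate dehydrogenase, fell by 0.41 ± 0.13 (adjusted p = 0.042), a call lost in 11 of 18 fits that left 1 library out (adjusted p = 0.0899 without y1_low replicate 1). Of 13 mitochondrially encoded messages, 0 passed by edgeR and all 13 were higher at 37.5 nM (median 0.33, camera adjusted p = 0.00958, adjusted p = 0.905 with an estimated correlation). For example, mt-atp8 (ENSDARG00000063910) had a log2 change of 0.48 ± 0.17 (adjusted p = 0.0681) and MT-ND1 (ENSDARG00000063895) one of 0.17 ± 0.19 (adjusted p = 0.579).

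Some genes on the lists of blood cells, and of complement and coagulation, rose at 37.5 nM. In the erythrocyte list, 5 of 17 genes rose and 12 did not pass (10 rose adjusted over the list alone), with a median of 0.89 (camera adjusted p = 0.000496, 0.857 with an estimated correlation and 0.05999 by exact permutation). SLC4A1 (ENSDARG00000012881), the anion exchanger of red cells, rose by 1.66 ± 0.37 from 5.60 ± 1.46 to 17.7 ± 12.7 CPM (adjusted p = 0.0107, 7 of 9 fish above all others), and nt5c2l1 (ENSDARG00000034852) rose by 1.69 ± 0.38 (adjusted p = 0.011). The globin HBE1 (ENSDARG00000089087, a symbol shared by 3 genes) rose by 1.59 ± 0.44 (adjusted p = 0.0278), and this call was lost in 5 of 18 fits that left 1 library out (adjusted p = 0.0618 without y1_high replicate 8). In the thrombocyte list, 2 of 9 genes rose (2 adjusted over the list alone) and the median was 0.83 (camera adjusted p = 0.0296, 0.857 with an estimated correlation and 0.140 by exact permutation). They were the thrombopoietin receptor mpl (ENSDARG00000039222, 1.05 ± 0.31) and its ligand thpo (ENSDARG00000079158, 1.098 ± 0.34), whose calls were lost in 7 and 12 of 18 such fits. In the complement and coagulation list, 3 of 56 genes rose (0 adjusted over the list alone), among them c7a (ENSDARG00000042172) by 0.71 ± 0.20 and VTN (ENSDARG00000055388, shared symbol) by 0.57 ± 0.17, with calls lost in 8 and 13 fits. Its median was 0.23 (camera adjusted p = 0.00972, 0.905 with an estimated correlation).

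Lists tied to growth and acute signals also passed camera with the preset correlation. In the immediate early list, 2 of 32 genes rose (1 adjusted over the list alone, median 0.30, camera adjusted p = 0.0219, 0.857 with an estimated correlation). One was mcl1a (ENSDARG00000009779), an inhibitor of apoptosis, which rose by 0.96 ± 0.19 (adjusted p = 0.00697) with all 9 fish above all 9 others. The other was BTG1 (ENSDARG00000027249), at 0.60 ± 0.18, whose call was lost in 14 of 18 fits. In the p53 and senescence list, 0 of 29 genes rose and 1 fell (1 adjusted over the list alone) although the median was 0.19 (camera adjusted p = 0.0451, 0.857 with an estimated correlation). The gene that fell was LMNB1 (ENSDARG00000044299), the nuclear lamina protein lamin B1 whose loss marks senescent cells, by 1.57 ± 0.43, a call lost in 4 of 18 fits. In the growth hormone and IGF list 0 of 32 genes passed (0 adjusted over the list alone, median 0.23, camera adjusted p = 0.00774, 0.857 with an estimated correlation), with values of 1.35 ± 0.46 for cishb (ENSDARG00000016773) and 0.81 ± 0.29 for INSR (ENSDARG00000011948, shared symbol). Among 80 cytosolic ribosomal proteins 0 passed, and all 80 were higher at 37.5 nM with library-wide TMM scaling (median 0.11, camera adjusted p = 0.00657, 0.905 with an estimated correlation), such as RPL31 (ENSDARG00000053365) at 0.19 ± 0.11. Their median was 0.29 in the lower series and −0.00 in the upper.

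In the lysosome and autophagy list, 3 of 55 genes rose and 4 fell (6 and 5 adjusted over the list alone). The median was 0.22, the mean −0.03, and camera called the list higher (adjusted p = 0.0219, 0.857 with an estimated correlation). The proton pump subunits ATP6V0D1 (ENSDARG00000069090) and ATP6V1A (ENSDARG00000034534, shared symbol) fell by 0.49 ± 0.12 and 0.89 ± 0.22. In the cell cycle list 2 of 47 genes fell (1 adjusted over the list alone), namely MCM5 (ENSDARG00000019507), a subunit of the replicative helicase, by 1.497 ± 0.33, and MCM2 (ENSDARG00000102798), which fell by 2.43 ± 0.76, the latter call lost in 13 of 18 fits. The median of that list was −0.21, −1.79 in the lower series and 0.19 in the upper (camera adjusted p = 0.0219, 0.905 with an estimated correlation). In the endocrine pancreas list 0 of 9 genes passed (median −1.69, camera adjusted p = 0.0219, 0.857 with an estimated correlation), with medians of −4.56 in the lower series and 2.11 in the upper. Its lowest p-values were those of ghrl (ENSDARG00000054239) at −1.66 ± 0.89 and sst2 (ENSDARG00000014190) at −2.01 ± 1.14. Without y1_high replicate 5 they stood at −2.64 and −4.03. Leaving out 1 library at a time, camera lost the p53, immediate early and cell cycle lists in 11, 6 and 4 of 18 fits (adjusted p = 0.138, 0.139 and 0.321 without y1_high replicate 6, y1_high replicate 5 and y1_low replicate 6) and the thrombocyte list in 3 (0.0776 without y1_high replicate 9).

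HKDC1 (ENSDARG00000038703), which belongs to the hexokinase family, fell by 4.06 ± 0.80 from 319 ± 357 to 19.1 ± 13.2 CPM, and the mitochondrial chaperonin HSPD1 (ENSDARG00000056160) by 1.93 ± 0.42 (adjusted p = 0.00725 and 0.00962). Among the genes with the highest changes, the clock repressor nfil3-5 (ENSDARG00000094965) rose by 2.08 ± 0.46, the kinases wnk4b (ENSDARG00000088967) and SIK1 (ENSDARG00000058606) by 1.63 ± 0.31 and 1.59 ± 0.38, and the ubiquitin ligase RNF24 (ENSDARG00000036965) by 1.91 ± 0.46. The transcription factor MYC (ENSDARG00000007241, shared symbol) rose by 2.4045 ± 0.68 and ccdc141 (ENSDARG00000095675) by 1.92 ± 0.56, with calls lost in 6 and 10 of 18 fits. The heat shock genes hsp70.3 (ENSDARG00000021924) and HSPA2 (ENSDARG00000092362) had log2 changes of −6.25 ± 1.32 and −4.78 ± 1.05. LRIT3 (ENSDARG00000055463) and the acyl-CoA synthetase ACSBG2 (ENSDARG00000004094) fell by 5.05 ± 1.33 and 3.81 ± 1.08, and with number series as a covariate their adjusted p-values were 0.11 and 0.327. Without y1_low replicate 4, LRIT3 stood at −3.46 (adjusted p = 0.0731). Single libraries set 4 further calls. Without y1_low replicate 6 the log2 changes of CUBN (ENSDARG00000087013), ctsbb (ENSDARG00000101051) and dab2 (ENSDARG00000031761) went from −7.37, −7.05 and −3.75 to 0.40, 0.95 and 0.35, and without y1_high replicate 5 that of MYL1 (ENSDARG00000017441) went from 3.65 to −0.09. Of the genes named in advance, kdrl (ENSDARG00000105215) stood at −0.07, CYP1A1 (ENSDARG00000098315) at 0.19, vtg1 (ENSDARG00000092233) at −0.16, PCK1 (ENSDARG00000013522) at −0.79 and cdkn1a (ENSDARG00000076554) at 0.75, none of them past the edgeR threshold.

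**Figure D2:**
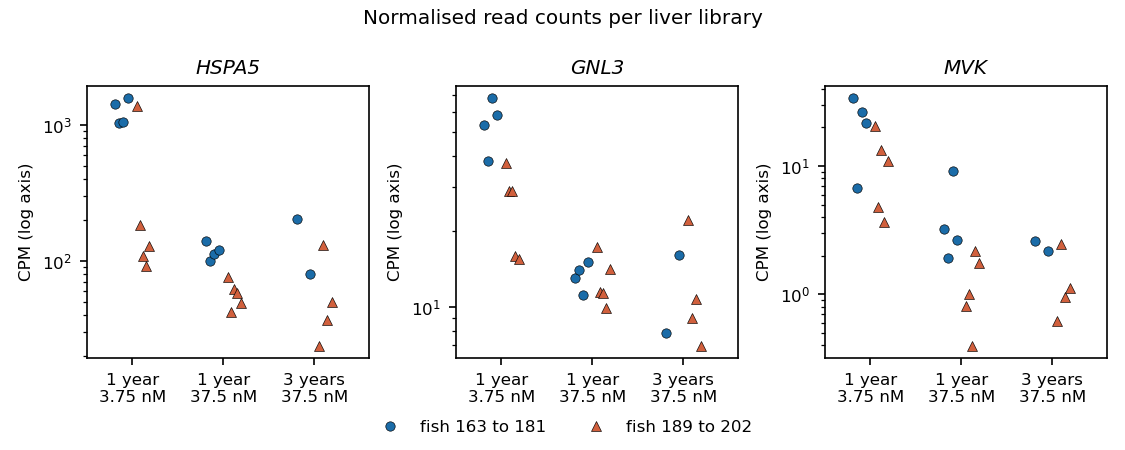
CPM of HSPA5, GNL3 and MVK in each library (vertical axis logarithmic) for 1-year fish at 3.75 nM and 37.5 nM and 3-year fish at 37.5 nM, with circles for fish 163 to 181, triangles for fish 189 to 202, and 1 point per fish. All 3 genes were lower at 37.5 nM, GNL3 at 13.3 against 37.5 CPM and with 8 of 9 fish below every fish at 3.75 nM.

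Across all genes, 1760 of 15465 passed edgeR's two-sided quasi-likelihood test at an adjusted p below 0.05, of which 493 rose and 1267 fell, so 28.0% were higher. That share was 37.8% with upper-quartile factors and 19.2% with library size alone. The count was 2546 with number series as a covariate, 5291 in the lower number series alone (4 against 4) and 0 in the upper alone (5 against 5). In the upper series 1218 genes had an unadjusted p under 0.05 by edgeR, DESeq2 called 143, limma voom called 0, and the adjusted p of each named gene was 0.541 or more by edgeR. A term for the interaction of dose and number series passed for 1216 genes. HSP90AA1 was −5.86 in the lower series and −0.72 in the upper (interaction adjusted p = 0.000128), while HSPA5 was −3.29 and −2.64 (0.724). The size of the upper series change of HSPA5 rested in part on fish 189 (y1_low replicate 5) and was −1.17 without it. Its direction did not rest on that fish. The remaining upper series y1_low fish stood at 92.1 to 184 CPM, above every upper series y1_high fish (42.5 to 76.0 CPM). With number series as a covariate, HSP90AA1, hsp70.3 and HSPA2 stood at −2.90, −3.80 and −2.87. Leaving out y1_low replicate 1, 2, 3 or 4, all of the lower series, gave 954, 1104, 917 and 909 genes. Intestine markers scored above 2 in y1_high replicates 5 and 7 and y1_low replicates 3, 6 and 8. Without these 5 libraries 1275 genes passed, 1078 of them among the 1760, but several calls near the threshold ended, among them nfil3-5 (0.0526), EBP (0.0537), PSMC3 (0.0512) and ATP6V1A (0.0834). The fish at 3.75 nM were deposited in a table of their own, so any difference between the 2 deposited sets could not be told apart from dose.

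The second comparison, named in the series title, set 3-year fish (n = 6) against 1-year fish (n = 9), all at 37.5 nM, and the sign of every change in it is 3 years minus 1 year. TENM2 (ENSDARG00000011171), a transmembrane adhesion protein known from neurons, was almost absent at 1 year and present in all 6 older fish, with 0.183 ± 0.106 and 19.2 ± 13.7 CPM (log2 change 6.70 ± 0.50, edgeR adjusted p = 1.2e-05). FBLIM1 (ENSDARG00000071558), which links integrin adhesions to actin filaments, fell by 2.85 ± 0.30, from 19.3 ± 7.30 to 2.66 ± 0.972 CPM (adjusted p = 0.000426, all 6 fish below all 9). The p53-induced antiproliferative gene BTG2 (ENSDARG00000020298) fell by 2.45 ± 0.33, from 17.97 ± 7.19 to 3.28 ± 0.922 CPM (adjusted p = 0.0036, 5 of 6 fish, with y1_high replicate 1 at 4.13 CPM). Of 50 gene lists, 10 passed camera with its preset correlation, but 0 passed with an estimated correlation, by fry or by exact permutation of all fish.

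Among the genes with the highest changes, loxl2a (ENSDARG00000044010), a lysyl oxidase that crosslinks collagen, rose by 3.61 ± 0.54 from 15.2 ± 7.41 to 185 ± 131 CPM (adjusted p = 0.00566, 5 of 6 fish above all others). The asparaginase ASPG (ENSDARG00000052942) rose by 2.45 ± 0.40, the endocannabinoid enzyme DAGLA (ENSDARG00000062956) by 2.51 ± 0.45 and the membrane protein ITM2C (ENSDARG00000039650, shared symbol) by 2.097 ± 0.36 (adjusted p = 0.00784, 0.0121 and 0.00944). The chemokine ccl34b.4 (ENSDARG00000094002) rose by 3.45 ± 0.71, ifi44a8 (ENSDARG00000093857) of an interferon-induced family by 2.88 ± 0.60 and the receptor kinase RET (ENSDARG00000055305) by 2.86 ± 0.60, and each call was lost in 2 of 15 fits that left 1 library out. Without y3_high replicate 3 the adjusted p of ccl34b.4 was 0.0579, and without y3_high replicate 5 those of ifi44a8 and RET were 0.0681 and 0.0745. SLC7A14 (ENSDARG00000010816) rose by 2.103 ± 0.46 and the semaphorin receptor PLXNB1 (ENSDARG00000075821, shared symbol) by 1.78 ± 0.41, with calls lost in 7 and 9 of 15 fits.

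Among the genes with the lowest changes, SELE (ENSDARG00000042138), the endothelial adhesion molecule E-selectin, fell by 3.27 ± 0.57 from 32.7 ± 25.1 to 3.39 ± 2.548 CPM (adjusted p = 0.0102, 6 of 6 fish below all others). The Wnt carrier WLS (ENSDARG00000009534) fell by 1.99 ± 0.31, XRCC5 (ENSDARG00000099298), a subunit of the Ku protein that repairs DNA breaks, by 1.81 ± 0.34, and the zinc receptor GPR39 (ENSDARG00000102888) by 1.63 ± 0.28 (adjusted p = 0.00566, 0.0149 and 0.00944, 6 of 6 fish each). The lipogenic regulator mid1ip1l (ENSDARG00000018145) fell by 1.65 ± 0.32 (adjusted p = 0.0185). Importin IPO8 (ENSDARG00000058159) fell by 2.11 ± 0.41, CASKIN2 (ENSDARG00000043818) by 1.82 ± 0.36 and B3GNT5 (ENSDARG00000018971, shared symbol) fell by 1.804 ± 0.38, and without y3_high replicate 5 their adjusted p-values were 0.0506, 0.0572 and 0.0696. In a fit of all 24 libraries the calls of mid1ip1l, GPR39, CASKIN2, B3GNT5 and ifi44a8 ended (adjusted p = 0.126, 0.0738, 0.0568, 0.0972 and 0.0555).

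In the p53 and senescence list, 3 of 30 genes fell, 0 rose and 27 did not pass (5 fell adjusted over the list alone), with a median of −0.30 (camera adjusted p = 0.000495, 0.886 with an estimated correlation). They were BTG2, the stress-inducible sestrin sesn2 (ENSDARG00000070012), which fell by 1.01 ± 0.17 (adjusted p = 0.00784, 6 of 6 fish), and the cyclin kinase inhibitor cdkn1a, which fell by 1.42 ± 0.33 (adjusted p = 0.0407, lost in 11 of 15 fits). Levels of sesn2 and cdkn1a were low, at 3.01 and 3.36 CPM at 1 year and 1.49 and 1.25 CPM at 3 years. The list had an adjusted p of 0.215 in an exact two-sided permutation of all fish and 0.0265 in one within number series, with medians of −0.56 and −0.36 in the lower and upper series. In the list of mitochondrial stress and the integrated stress response, 1 of 30 genes fell, again sesn2 (6 fell adjusted over the list alone, median −0.30, camera adjusted p = 0.000993, 0.886 with an estimated correlation), and atf4b (ENSDARG00000038141) had a value of −0.65 ± 0.17 (adjusted p = 0.0629). In the cholesterol list 0 of 25 genes passed (3 fell adjusted over the list alone, median −0.97, camera adjusted p = 0.000563, 0.886 with an estimated correlation, 0.517 by exact permutation), with EBP at −1.71 ± 0.50 (adjusted p = 0.0821). In the immediate early list 2 of 33 genes fell, BTG2 and JUND (ENSDARG00000067850, by 0.94 ± 0.18, adjusted p = 0.0146), and 4 fell adjusted over the list alone (median −0.43, camera adjusted p = 0.00285, 0.886 with an estimated correlation).

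In the T and NK cell list, 1 of 23 genes rose and 22 did not pass (6 rose adjusted over the list alone), with a median of 0.53 (camera adjusted p = 0.000993, 0.886 with an estimated correlation, 0.517 by exact permutation). It was gzmk (ENSDARG00000028780), a protease of cytotoxic lymphocytes, which rose by 4.44 ± 0.76 from 0.103 ± 0.127 to 2.23 ± 1.7997 CPM (adjusted p = 0.00944, 6 of 6 fish). The interleukin receptor il7r (ENSDARG00000078970) had a value of 3.50 ± 0.86 (adjusted p = 0.0531), 1.72 without y3_high replicate 2. Among respiratory chain subunits, 0 of 38 complex I genes passed (0 adjusted over the list alone, median 0.10, camera adjusted p = 0.024). In complexes II to V, 1 of 46 genes rose (3 adjusted over the list alone, median 0.08, camera adjusted p = 0.0339). Each list had an adjusted p of 0.886 with an estimated correlation and 0.685 by exact permutation. The ATP synthase subunit atp5mc1 (ENSDARG00000056008) rose by 0.58 ± 0.14 (adjusted p = 0.0426, lost in 12 of 15 fits), and NDUFAB1 (ENSDARG00000058463) and NDUFV2 (ENSDARG00000013044) had values of 0.51 ± 0.14 and 0.30 ± 0.11. The cell cycle list (0 of 51 passed, median 0.33, camera adjusted p = 0.0245) had medians of 2.45 in the lower series and −0.80 in the upper. The circadian list (0 of 40, median −0.24, camera adjusted p = 0.0281) and the erythrocyte list (0 of 18, median 0.46, camera adjusted p = 0.0302) had upper series medians of −0.13 and 0.00. The last 3 lists each had 0 members adjusted over the list alone and an adjusted p of 0.886 with an estimated correlation, with MCM2 at 1.26 ± 0.68, cry3a (ENSDARG00000069074) at −0.41 ± 0.14 and gata1a (ENSDARG00000013477) at 1.32 ± 0.49. Leaving out 1 library at a time, camera kept the p53, cholesterol, mitochondrial stress, immediate early and T cell calls in 15 of 15 fits. It lost complexes II to V in 8, complex I in 7, cell cycle in 6, erythrocytes in 3 and the circadian list in 2 (adjusted p = 0.266 and 0.18 without y1_high replicate 9, 0.552 without y3_high replicate 2, 0.136 without y3_high replicate 1 and 0.168 without y3_high replicate 2).

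**Figure D3:**
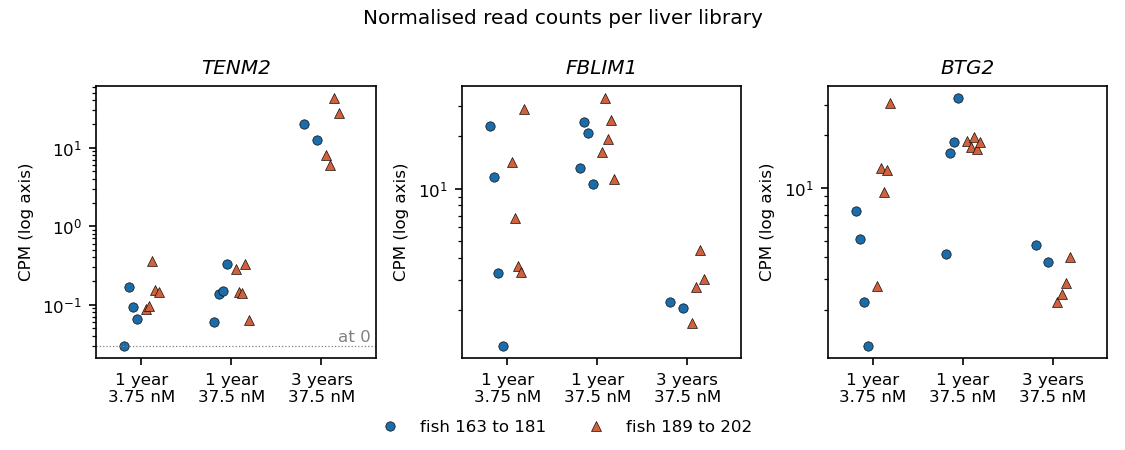
CPM of TENM2, FBLIM1 and BTG2 in each library (vertical axis logarithmic, a library at 0 drawn on the dotted line) for the 3 groups, with circles for fish 163 to 181, triangles for fish 189 to 202, and 1 point per fish. TENM2 averaged 19.2 CPM in the 6 three-year fish and 0.183 CPM in the 9 one-year fish at 37.5 nM, without overlap, while FBLIM1 and BTG2 in the fish at 3.75 nM spread over the range of both other groups.

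The endothelial gene kdrl, whose promoter drives the transgene of the older fish, had a log2 change of 0.15 ± 0.14 (adjusted p = 0.599). CYP1A1 (−0.24), vtg1 (−0.07), HSPD1 (0.53), NDUFS1 (0.14), MT-ND1 (−0.08) and PCK1 (−1.77) did not pass either. HSPD1 stood at 0.15 without y3_high replicate 1, and PCK1 at −2.78 without y3_high replicate 4. Markers of intestine had a median of −3.55 over 24 genes, of which 0 passed over all genes and 15 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.0591, 0.685 by exact permutation). The difference came from y1_high replicates 5 and 7, where the markers scored 4.75 and 6.63. Without those libraries 208 genes passed, 158 of them among the calls below, and the calls of ccl34b.4 (0.0602), ifi44a8 (0.0536), SLC7A14 (0.0626) and PLXNB1 (0.0709) ended.

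Across all genes, 278 of 16159 passed edgeR's test, of which 145 rose and 133 fell, so 52.2% were higher (65.8% with upper-quartile factors). DESeq2 called 1197 and limma voom 853, and edgeR called 572 with number series as a covariate. The count was 13 in the lower series alone (2 against 4) and 30 in the upper alone (4 against 5), and the interaction of age and number series passed for 0 genes by edgeR (1521 at an unadjusted p under 0.05, no other tool run). TENM2 passed in both series, at 6.53 (adjusted p = 0.0142) and 6.73 (adjusted p = 0.0161). FBLIM1 stood at −3.04 and −2.84 and BTG2 at −2.096 and −2.67 in the lower and upper series, and both passed in the upper. Leaving out y3_high replicates 4, 5 or 6 or y1_high replicate 5 gave 559, 115, 139 and 167 genes.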

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

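The tests of haplotype neighbours and of marker covariates in the age comparison were chosen only after the result they test was seen.

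The heat shock genes that fell at 37.5 nM did so mainly in the lower number series (HSP90AA1 at −5.86 against −0.72), where 5291 genes passed against 0 in the upper. RNA of intestine or exocrine pancreas was argued against for the 74.4% of lower series calls that remained with those marker scores as covariates. That test was weak for intestine. Among the 1-year lower series fish only y1_low replicate 3 scored high (5.44, against −0.95 to 0.76), so the covariate mostly set that library apart. RNA of islets stayed open for the lower series calls outside the heat shock, ER response, cholesterol and ribosome biogenesis lists. It was not tested there. Endocrine pancreas scores separated the doses in the lower series (1.51 to 4.59 at 3.75 nM, −1.96 to 0.54 at 37.5 nM) and could not serve as a covariate there. For those lists other fish argued against islet RNA. Endocrine scores were 3.88, 1.58 and 1.53 in y1_high replicates 5 and 7 and y3_high replicate 5. Their heat shock scores were −0.02, −0.49 and −0.33, against 1.53 to 2.00 in the lower series at 3.75 nM. An unnamed difference between the series that acted at 3.75 nM stayed open too, with 1885 genes past the threshold between the series within those fish (4956 at an unadjusted p under 0.05) and 5 within the 1-year fish at 37.5 nM (3266). A dose difference of the same direction in both series stayed open for the lower series calls as a set. Over them the mean signed log2 change in the upper series was 0.22, and 80.5% had the same sign. The one-sided exact permutation p was 0.0675 (17 of 252 splits as large in the same direction, smallest possible 0.00397). The ER response and cholesterol lists were lower at 37.5 nM in the upper series too, without overlap between fish. ER response scores there were −0.21 to 1.11 at 3.75 nM and −0.68 to −0.42 at 37.5 nM. Cholesterol scores were 0.37 to 1.56 and −0.81 to 0.08. Scores of ribosome biogenesis and heat shock overlapped between the doses there. These lists were singled out by tests that included the same fish.

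TENM2 (6.70), FBLIM1 (−2.85) and IPO8 (−2.11) separated all 3-year from all 1-year fish at 37.5 nM without overlap of levels. A strain haplotype around the transgene could give such differences. The test by neighbouring genes was void, because 75.9% of the called genes could be placed by name where 80% was needed, so this explanation stayed open. Low FBLIM1 levels were not limited to 3-year or transgenic fish. FBLIM1 stood at 3.28, 1.25, 3.58 and 3.31 CPM in y1_low replicates 3, 4, 7 and 8, against 1.69 to 4.45 CPM in 3-year fish. The other y1_low fish had 6.78 to 28.8 CPM. TENM2 was at most 0.365 CPM in the y1_low fish. RNA of intestine or exocrine pancreas was argued against for the 60.1% of calls that remained with marker scores as covariates, but not for the others. TENM2 passed in all 30 alternative fits, the one with marker covariates among them. Over 2410 genes with an unadjusted p under 0.05 in the lower series, the mean signed log2 change in the upper was 0.34 (one-sided exact permutation p = 0.0159, 2 of 126 splits), and 72.0% had the same sign.

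Random regrouping of the fish gave as many genes only for the real grouping itself, 1 of 100 splits, in both comparisons (at most 55 genes for age and 680 for dose in any other split). For camera's lists at the preset correlation, 97 of 100 splits gave as many as the 10 age lists (up to 27) and 36 of 100 as many as the 19 dose lists (up to 29). Chance is therefore not excluded for the number of lists. By exact permutation of all fish 0 age lists and 4 dose lists passed, and of these only ribosome biogenesis passed in all 18 fits that left 1 library out.

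Single fish departed from the rest of their group in 19 of 322 checks. By chance 16.1 would pass, had the checks been independent and their genes picked without these data. Many of the genes were named for extreme changes in the same fish, which 1 fish can set, as for CUBN, ctsbb, dab2 and MYL1. The 16.1 is therefore no measure of chance here. The cholesterol score was 1.45 in y1_high replicate 3 (−0.87 to 0.17 in the others), the growth hormone and IGF score −0.49 in y1_high replicate 7 (0.00 to 0.38), and the lysosome score 0.98 in y1_low replicate 6 (−0.70 to 0.03). In y1_low replicate 6, CUBN, ctsbb and dab2, genes of endocytic epithelium, stood at 889, 1096 and 381 CPM (at most 0.648, 0.990 and 3.91 in the others), with VTN at 93.8 (137 to 187) and CYP1A1 at 220 (510 to 1082). In y1_high replicate 5, the muscle gene MYL1 stood at 103 CPM (0.604 to 2.12), sst2 at 14.2 (0.0891 to 1.902) and atp5mc1 at 67.5 (99.7 to 135). In y1_high replicate 9, cry3a stood at 425 CPM (586 to 688), cyp2k19 at 98.0 (135 to 174) and ahr2 at 126 (79.2 to 96.9). Others were BTG2 at 4.13 CPM in y1_high replicate 1 (16.0 to 32.4), cyp2p10 at 5.99 in y1_high replicate 3 (2.45 to 3.43), HKDC1 at 52.0 in y1_high replicate 7 (8.60 to 20.0), SLC20A1 at 36.2 in y1_low replicate 9 (135 to 447) and PCK1 at 22.6 in y1_low replicate 5 (548 to 5551).

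The interaction of dose and number series passed for 1216 genes. Among the named heat shock genes its adjusted p was 0.00649 for hsp70.3, 0.000128 for HSP90AA1, 0.00451 for HSPA2 and 0.00443 for HSPA4. Among metabolic genes it was 0.0345 for HKDC1, 0.0137 for ACSBG2, 0.0179 for cycsb, 0.00459 for higd1a, 0.0177 for prdx1 and 0.0117 for PGD. It was 0.00203 for ccdc141, 0.0235 for RNF24, 0.0458 for CUBN, 0.0474 for sst2 and 0.0137 for NR3C1. INSR stood at 1.78 in the lower and 0.29 in the upper series (0.0378), BTG1 at 1.14 and 0.31 (0.0474) and HDAC1 at −0.78 and −0.21 (0.0488).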

How the results depend on the processing

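The fits without libraries high in intestine markers, with marker covariates, without fish 189, and with DESeq2 or voom per number series, and both exact list permutations, were chosen only after the data were seen. No paired analysis was possible because the replicate numbers follow accession order and link no fish across groups. The fall of HSPA5, GNL3 and NOC3L with dose kept its sign in every setting, and so did the age differences of TENM2, FBLIM1 and BTG2. In the age comparison 278 genes passed, against 572 with number series as a covariate, 13 in the lower and 30 in the upper series alone, 1197 by DESeq2, 853 by voom, and 115 and 102 on deposited RPKM-named values plus 0.1 or 1. Its 10 lists became 0 with an estimated correlation, 0 by fry, 0 by exact permutation and 1 within number series. In the dose comparison 1760 genes passed, against 1131 without a filter, 5291 in the lower series (6102 by DESeq2, 5344 by voom) and 0 in the upper (143 by DESeq2, 0 by voom, 0 without fish 189), 2706 by DESeq2 and 3985 by voom. Its 19 lists became 0 with an estimated correlation, 4 by fry, 4 by exact permutation and 8 within number series. Leaving out 1 library gave 115 to 559 age genes, 6 to 14 age lists and 909 to 2518 dose genes. It moved age log2 changes of vtg1 from −1.09 to 0.30 and MT-ND1 from −0.16 to 0.0415, and dose log2 changes of MYL1 from −0.0852 to 3.97, CUBN from −7.54 to 0.40, ctsbb from −8.39 to 0.95, dab2 from −3.93 to 0.35 and vtg1 from −0.53 to 0.14.

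Values whose direction reversed in the age comparison were the cell cycle list in the upper series (adjusted p = 0.197), CCNE2 in the lower (0.62), vtg1 in the upper (0.13) and MT-ND1 by voom (0.0710), on RPKM-named values (0.16 and 0.16) and with marker covariates (0.0576). In the dose comparison, lists reversed in the upper series, with and without fish 189, were the cytosolic ribosomal proteins (adjusted p = 0.634 and 0.0281), cell cycle (0.335 and 0.130) and endocrine pancreas (0.802 and 0.719). In the lower series, MYL1 stood at −0.31 (DESeq2 −0.33), CUBN at 1.04 (DESeq2 1.03, voom 1.11) and dab2 at 0.0936 (DESeq2 0.0730, voom 0.15). In the upper series, and then without fish 189, ccdc141 stood at −0.18 and −0.30, ACSBG2 at 0.46 and 0.87, ghrl at 0.43 and 0.25 and sst2 at 2.11 and 1.91, with kdrl at 0.0654. By DESeq2 there, ccdc141 stood at −0.21, ACSBG2 at 0.44, ghrl at 0.39 and kdrl at 0.0391. By voom there, ccdc141 stood at −0.53, ACSBG2 at 0.83, dab2 at 0.13, sst2 at 1.57, LMNB1 at 0.38, CYP1A1 at −0.15, MT-ND1 at −0.0575, prdx1 at 0.28 and SLC20A1 at 0.11. With DESeq2 on all fish MYL1 stood at −0.11, CUBN at 0.36 and dab2 at 0.33, and without the libraries high in intestine markers CUBN stood at 0.45 and dab2 at 0.40.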

Other observations

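The marker covariates and the intestine score threshold described here were set only after the data were seen, and the test of list permutation within number series likewise.

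Several stress and fuel genes changed with dose outside the lists that passed as a whole. In the list of mitochondrial stress and the integrated stress response, 7 of 30 genes fell and 0 rose (12 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0544). ALDH1L2 (ENSDARG00000070230), a mitochondrial folate enzyme induced by ATF4, fell by 2.16 ± 0.39 from 9.63 ± 6.24 to 2.15 ± 0.678 CPM (edgeR adjusted p = 0.00663, n = 9 each), and HSPE1 (ENSDARG00000056167), the partner of HSPD1, by 1.62 ± 0.34 (adjusted p = 0.00856). The threonyl-tRNA synthetase TARS1 (ENSDARG00000013250) fell by 1.498 ± 0.28 (adjusted p = 0.00697). Of 25 genes of fatty acid and triglyceride synthesis 4 fell (7 adjusted over the list alone, camera adjusted p = 0.0763), among them MID1IP1 (ENSDARG00000019302), an activator of acetyl-CoA carboxylase, by 2.86 ± 0.63 and ELOVL5 (ENSDARG00000004979), a fatty acid elongase, by 1.61 ± 0.37. Of 41 NRF2 targets 4 fell and 1 rose (camera adjusted p = 0.513). The peroxiredoxin prdx1 (ENSDARG00000058734) fell by 3.31 ± 0.78 and PGD (ENSDARG00000015343) of the pentose phosphate pathway by 2.49 ± 0.64, at −0.47 and −0.35 in the upper series. LDHB (ENSDARG00000019644) fell by 1.54 ± 0.41 and the hypoxia-inducible higd1a (ENSDARG00000022303) by 1.499 ± 0.39, at −0.81 and −0.0656 in the upper series against −2.15 and −2.63 in the lower, while the mitophagy receptor BNIP3L (ENSDARG00000028067) rose by 1.15 ± 0.29. Without y1_low replicate 1 the adjusted p of LDHB was 0.0556, and without y1_low replicate 3 that of higd1a was 0.0525.

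Genes on the circadian list moved in both directions and a few vessel genes rose at 37.5 nM. In the circadian list 7 of 40 genes rose and 2 fell, and TARS1, the tRNA synthetase named above, was among those that fell. The median of the list was −0.02, its mean 0.06 and its camera direction up (adjusted p = 0.208). In the endothelium list 2 of 24 genes rose (camera adjusted p = 0.502), the apelin receptor aplnra (ENSDARG00000002172) by 2.94 ± 0.57, from 0.656 ± 0.518 to 5.04 ± 4.15 CPM, and the receptor kinase TIE1 (ENSDARG00000004105) by 0.73 ± 0.17, in 7 and 8 of 9 fish beyond the other group. The matrix protease MMP14 (ENSDARG00000008388) rose by 1.13 ± 0.27, the iron exporter SLC40A1 (ENSDARG00000000241) by 1.46 ± 0.43 and the glucocorticoid receptor NR3C1 (ENSDARG00000025032) by 0.66 ± 0.17. The call of SLC40A1 was lost in 8 of 18 fits that left 1 library out (adjusted p = 0.0773 without y1_high replicate 6). The xenobiotic receptor ahr2 (ENSDARG00000021833) rose by 0.53 ± 0.14 and cyp2k19 (ENSDARG00000101861) fell by 0.84 ± 0.17, in a list where 5 of 44 genes rose and 1 fell. The deacetylase HDAC1 (ENSDARG00000015427) fell by 0.52 ± 0.12. In 3-year fish the cytochrome cyp2p10 (ENSDARG00000042990) rose by 1.404 ± 0.22 (adjusted p = 0.00566, n = 6 and 9) and cyp2ad2 (ENSDARG00000021172) by 0.92 ± 0.22, the latter lost in 13 of 15 fits that left 1 library out. The lipid droplet coat PLIN2 (ENSDARG00000042332) fell by 1.39 ± 0.31, GPAM (ENSDARG00000074169) of triglyceride synthesis by 1.04 ± 0.22, higd1a by 1.18 ± 0.23, GCLC (ENSDARG00000013095) of glutathione synthesis by 0.54 ± 0.12, the Hsp90 activator AHSA1 (ENSDARG00000100317) by 0.59 ± 0.12 and LAMP2 (ENSDARG00000014914) by 0.40 ± 0.09. The autophagy kinase ULK1 (ENSDARG00000074481) rose by 0.64 ± 0.15, and irf1a (ENSDARG00000043492) fell by 3.42 ± 0.75 from only 1.34 to 0.122 CPM. Their calls were lost in 11 and 6 of 15 fits. The calls of PLIN2, GCLC, LAMP2, GPAM and AHSA1 were lost in 7, 5, 4, 3 and 1 of them, mostly without y3_high replicate 5 or 6 (adjusted p of GPAM 0.0679 without replicate 5, of PLIN2 0.0767 without replicate 6). Of the names with values short of the threshold, the dose change of MT-ATP6 (ENSDARG00000063911) was 0.41, and the age changes of CCNE2 (ENSDARG00000098529), NAMPT (ENSDARG00000030598) and cox6a1 (ENSDARG00000022438) were −1.04, −0.53 and 1.39.

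The marker lists were read as possible sources of RNA from other tissue. Levels below are from the 18 libraries of 1-year fish, so 3-year fish are not covered by them. Of 31 intestine genes 3 stood in another list, and of the 23 tested 10 had a mean of at least 4 CPM even in libraries low in intestine markers. The most abundant, chia.3, reached 10864 CPM in y1_high replicate 7 with a median of 0.866 over the 18 libraries. Of 35 exocrine pancreas genes 0 stood in another list, and 31 of 32 tested reached 4 CPM in the libraries low in intestine markers. The mean of prss1 was 1063.9 CPM there (median 749.5 over the 18 libraries), so pancreatic RNA was measurable in those libraries too. The islet gene ins reached 472 CPM in y1_low replicate 3 (median 3.60), while the hepatocyte gene tfa had a median of 39875 CPM. Intestinal RNA could account for part of the age calls, and 224 genes passed with marker scores as covariates, 167 of them among the 278.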
